A study of Caenorhabditis elegans with 2 samples.

How the data were processed

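RPC-1, the largest subunit of RNA polymerase III, was profiled by chromatin immunoprecipitation and sequencing in young adult hermaphrodites of Caenorhabditis elegans carrying a temperature-sensitive glp-1 allele. Whole animals expressed RPC-1 with a C-terminal GFP and FLAG tag, and an antibody against GFP was used, per the labels. There was 1 group with 2 samples, labelled biological replicates 1 and 3, from separate biosamples. Per the labels, chromatin was sheared with a Bioruptor in replicate 1 and with a microtip in replicate 3, so this technical difference goes together with the replicate.

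The authors deposited peak lists on the ce11 and ce10 builds. Per the file headers, 1 list was called for each sample, 1 list was called on both samples pooled, and an IDR list was derived from these. The lists per sample and the pooled list hold at most 30000 peaks each. IDR, the irreproducible discovery rate, is a measure of how well the ranks of peaks repeat between replicates, and a peak of the IDR list need not be in the list of each replicate. Each deposited list gives a signal value per peak, which is the authors' own value relative to a control alignment, and the −log10 of a q-value. The signal was used to describe, rank or filter peaks and to compare groups of peaks or genes within the list it came from. Its scale differed between lists, so signals of the replicates were related only by their ranks across genes. The aligner and peak caller are not given in the sources used here. The control alignment was not analysed here. The lists hold no read counts, so the depth of each sample is unknown and no interval that needs depth is given.

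The ce11 lists were matched to the RefSeq annotation of the same assembly, and the ce10 lists were used only for counts. A gene was called bound when an IDR summit lay within 250 bp of its body. RNA polymerase III genes were nuclear tRNA genes, 5S rRNA genes, U6 snRNA genes and other RNA polymerase III RNAs (RNase P RNA, RNase MRP RNA, Y RNA and signal recognition particle RNA). U6 genes were recognised by a conserved core of 23 bases. SmY RNA genes were kept as a class of their own, which was decided after the annotation was read. Promoters ran from 500 bp upstream to 250 bp downstream of the annotated 5′ end of protein-coding genes, and were tested with peaks at least 500 bp from RNA polymerase III genes and tRNA pseudogenes. The 10 gene lists tested at promoters were RNA polymerase III subunits and factors, ribosomal proteins, aminoacyl-tRNA synthetases, histones, heat shock proteins, germline, intestine, muscle, neuron and collagens.

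Shares of genes carry 95% Clopper-Pearson intervals. Classes, gene lists and groups of tRNA genes were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family. Peak positions were compared with 1000 random placements on the same chromosome, one-sided. Medians, isotype shares and rank correlations were tested with 100000 permutations, two-sided, or by exact enumeration where a group held fewer than 10 genes. The B-box GGTTCGANNCC was searched on both strands with at most 1 mismatch outside N, and summit windows were set against windows 2000 bp to either side by McNemar's exact test; the larger of the 2 p-values is given. Sequence repetition was measured as the percent of 36-base words within 250 bp that occur once in the genome. Intervals of differences in the closing section are percentile bootstrap intervals from 10000 draws, added after a first look at those differences. A p-value over peaks or genes describes these lists, not animals, and genes are not independent replicates.

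The comparisons, lists, tests and alternatives were chosen before the data were examined, except where the text says otherwise. Named genes were those of the 10 highest-signal IDR peaks, the 10 highest-signal bound tRNA genes, every bound U6 gene and other RNA polymerase III RNA, and up to 4 bound 5S rRNA genes. Up to 4 bound genes with the highest signal in each other RNA class were added, with the 10 protein-coding genes of highest promoter signal and up to 4 bound genes of each protein-coding list. The text gives examples from these. Replicate peaks counted as shared when their summits lay within 250 bp, and alternatively when the intervals overlapped by 1 bp or by 50% of the shorter peak. Alternatives changed the distance, the list, the promoter window, the merging of neighbouring genes and the chance model, or left out a replicate by taking the top 1860 peaks of the other.

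The statistics were tested on simulated data: 200 of 200 tRNA genes given a simulated peak, among 612, were recovered. These peaks were placed at the middle of the genes, so the recovery was certain and checks only the counting. Without an effect, the highest share of runs with p under 0.05 was 7%, in the isotype test. Bound genes were drawn independently in those runs, whereas neighbouring tRNA genes can share a peak. The 7% therefore does not show how the tests of X and of isotypes behave on such clustered genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.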

Results

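RPC-1 binding was measured in 2 samples of whole young adult worms, replicates 1 and 3 of a single group. The IDR list on ce11 held 1860 peaks, and that on ce10 held 1886. On ce11, the lists of replicates 1 and 3 and the pooled list held 29914, 30000 and 30000 peaks. The 1860 IDR peaks were also the 1860 peaks of highest signal in the pooled list. A summit within 250 bp was present for 1828 of them in the list of replicate 1 and for 1719 in that of replicate 3. Chromosome X carried 523 IDR peaks (28.1%; 29.5 per Mb), no autosome had more than 19.95 per Mb, and the mitochondrial genome carried 20. Peaks were called per sample and on the pooled samples, and the depth of the samples is unknown.

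The first comparison asked which RNA polymerase III genes RPC-1 occupied. Nuclear tRNA genes, which encode the adaptors of translation, were bound in 565 of 612 cases (92.3%; 95% Clopper-Pearson interval 89.9 to 94.3%). All 8 other RNA polymerase III RNA genes were bound: the RNase P RNA gene rpr-1, the RNase MRP RNA gene mrpr-1, the Y RNA gene yrn-1 and 5 signal recognition particle RNA genes. Of the 22 U6 snRNA genes, which encode the spliceosomal U6 RNA, 9 were bound (40.9%; interval 20.7 to 63.6%). Of the 16 annotated 5S rRNA genes, 2 were bound (12.5%; interval 1.55 to 38.3%). The median of unique 36-base words was 45.4% around bound and 7.78% around unbound 5S genes, and 82.7% around bound and 65.1% around unbound U6 genes; neither difference passed the exact permutation test (p = 0.183 and 0.132). Fewer than 70% unique words, a limit set after seeing the data, surrounded 13 of 14 unbound and 1 of 2 bound 5S genes, and 7 of 13 unbound and 1 of 9 bound U6 genes (Fisher's exact test, p = 0.242 and 0.0743).

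Altogether 554 of the 1860 IDR peaks (29.8%) had a summit within 250 bp of an RNA polymerase III gene. Random placements gave a mean of 7.60 peaks (0.408%), a 72.9-fold difference (one-sided permutation of peak positions, p = 0.001, the smallest that 1000 placements can give). Among the 100 strongest peaks, 63 lay at these genes. The fold depended on the setting: it was 141 at 100 bp, 42.7 at 500 bp, 127 in the upper 930 peaks and 14.1 against draws from the relaxed pooled list, while the counts at 100 and 500 bp were 543 and 563.

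**Figure D1:**
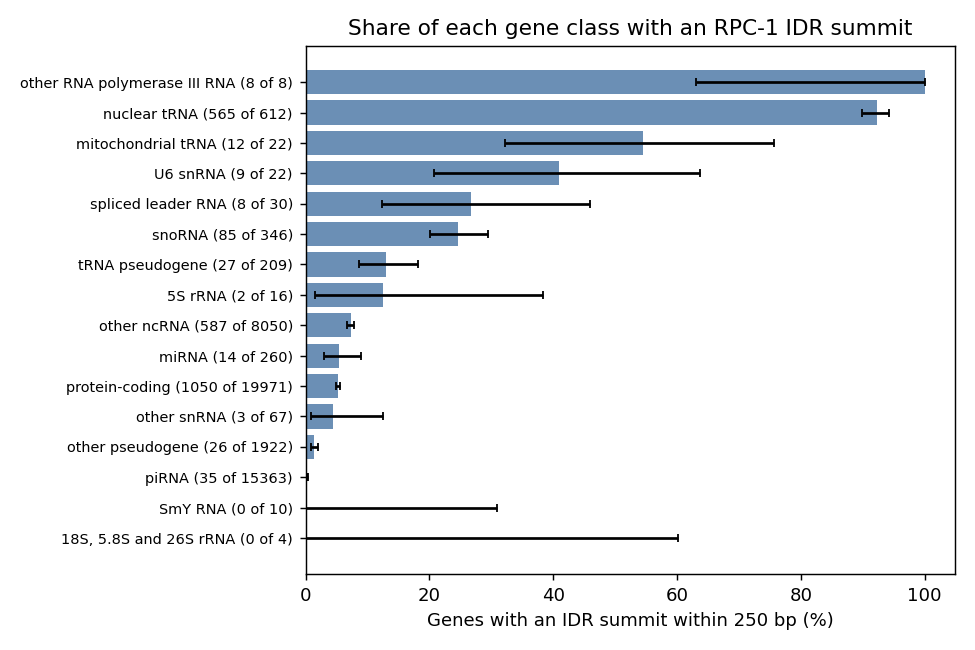
Percent of the annotated genes of each class with an IDR summit within 250 bp (horizontal axis), with bound and total genes beside each class name. Lines are 95% Clopper-Pearson intervals; nuclear tRNA genes stood at 92.3% and snoRNA genes at 24.6%.

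The strongest tRNA gene was C04A11.t1 (Leu; X, 13665555 to 13665673, intergenic), with an IDR signal of 14745 and rank 2 in the IDR list. It ranked 2 in each replicate as well. R01H5.t1 (Thr; X, 12563788 to 12563859, intergenic) followed with a signal of 9843, and the neighbours F15G9.t1 and F15G9.t2 (Ala), in an intron of him-4, shared a peak of 9596. H08J11.t2 and H08J11.t3 (Gln), in an intron of ajm-1, shared a peak of 9058. The summits of these shared peaks lay in F15G9.t1 and H08J11.t3. The other gene of each pair was counted through the 250 bp limit. The 10 strongest tRNA genes all lay on X. Among the other RNA polymerase III RNAs, srpr-1.1 (III, 4378909 to 4379206) had a signal of 5430 and rpr-1, in an intron of ints-8 on the opposite strand (I, 13463955 to 13464207), had 4809. The signals of srpr-2.2, srpr-2.1, mrpr-1, srpr-1.2, yrn-1 and srpr-3 were 4543, 3405, 2799, 1645, 1067 and 141. The bound U6 genes ranged from W05B2.8, in an intron of dhc-4 (6547), through F54D8.7 (1922) to F54C8.8 (91.0), and the last had no peak within 250 bp in replicate 3. The bound 5S rRNA genes rrn-4.12 and rrn-4.15 on V had signals of 226 and 203.

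The share of bound tRNA genes was compared between X, which holds 276 of them, and the autosomes. On X 256 genes were bound (92.8%) and on the autosomes 309 of 336 (92.0%), a difference of 0.789 percentage points (Fisher's exact test, two-sided, p = 0.762). By chromosome the share ran from 86.4% on I to 96.5% on II. Inside protein-coding genes 270 of 291 tRNA genes were bound (92.8%), and outside them 295 of 321 (91.9%; Fisher's exact test, p = 0.762). With tRNA genes merged into loci, the difference for X was 4.79 percentage points and passed the threshold (Fisher's exact test, p = 0.0450). A locus counted as bound if any of its genes was, so unbound genes beside bound ones no longer counted. This result is about loci and does not show that single tRNA genes on X were bound more often.

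Across 21 isotypes, His and Arg tRNA genes had the lowest shares bound, 15 of 20 (75%) and 36 of 44 (81.8%). Ser (39 of 39), Asp and Gln (27 of 27 each), Cys (13 of 13), Trp (12 of 12) and the single Sec gene were fully bound. The shares did not differ past the threshold (permutation test of the chi-square statistic, p = 0.056), and no isotype passed after Benjamini-Hochberg adjustment (Arg, raw p = 0.00973; His, raw p = 0.0109; adjusted p = 0.114 for both). Of the 5 unbound His genes, 4 lay in repeated sequence. The permutation test over isotypes passed at 100 bp (permutation test, p = 0.0062). It also passed in the top peaks of replicate 3 alone or of replicate 1 alone (permutation test, p = 0.008 and 0.042). At 500 bp and in merged loci the shares did not differ past the threshold (permutation test, p = 0.12 and 0.29). Outside repeated sequence, an alternative chosen after seeing the data, they did not either (permutation test, p = 0.17).

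Peaks at tRNA genes were stronger than the rest of the list. Their median signal was 2789 (534 peaks) against 100.1 for the other 1326 peaks, a ratio of 27.9 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). The direction was the same in the top peaks of each replicate alone, on that list's own scale. Of the 534 tRNA peaks, 514 lay in the upper 930 of the IDR list. A B-box, the internal promoter element of tRNA genes, lay within 250 bp of 745 of 1840 nuclear summits (40.5%), against 5.82% and 7.5% of the windows 2000 bp to either side (McNemar's exact test, p = 5.03e-129), a difference of 33.8 percentage points. Of the 745 summits, 469 were peaks at tRNA genes, and 536 of the 612 tRNA genes hold a B-box. The difference over all summits therefore largely restates that peaks lay at tRNA genes. Among peaks at least 500 bp from RNA polymerase III genes the difference was 15.1 points. A B-box was found at 87.8% of the peaks at tRNA genes, at 92.3% of the 26 peaks at tRNA pseudogenes and at 41.5% of the 82 peaks at snoRNA genes. Within the genes themselves, a B-box was found in 24 of 26 tRNA pseudogenes bound by peaks away from RNA polymerase III genes and in 179 of the other 183 (97.8%; Fisher's exact test, p = 0.163). Among 406 summits at protein-coding promoters with no small RNA gene, it was found at 4.93%, against 5.67% on both sides (McNemar's exact test, p = 0.755).

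**Figure D2:**
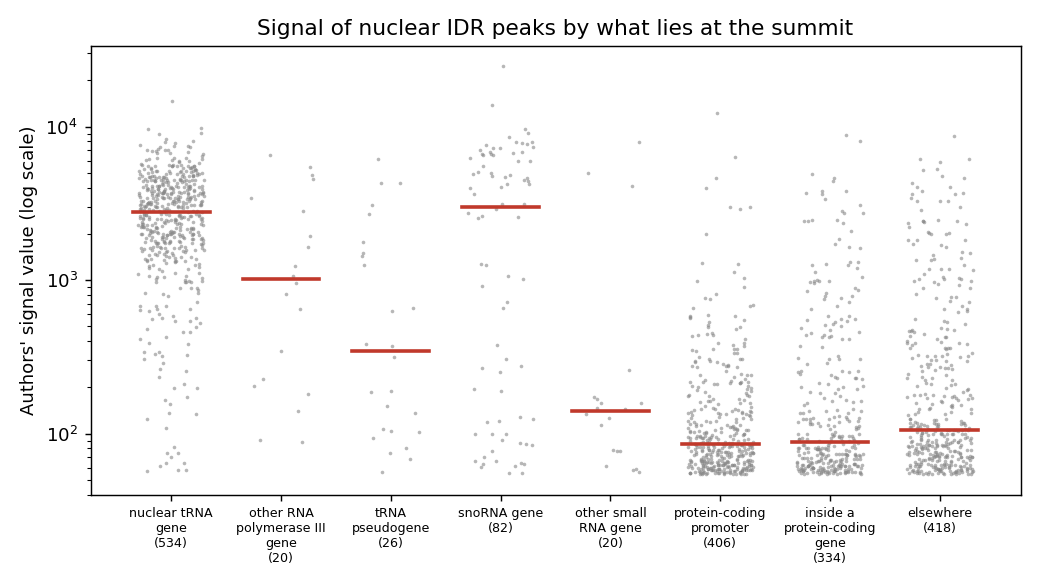
Signal of each nuclear IDR peak (points; the authors' value on a log axis) by what lies at its summit, with the number of peaks under each category and the median as a red line. The medians were 2789 at tRNA genes, 2996 at snoRNA genes and 84.8 at protein-coding promoters.

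Genes of small nucleolar RNAs, which guide modification of other RNAs, also had strong peaks, with a median signal of 3622 at bound genes against 2911 at bound tRNA genes. Of 346 snoRNA genes, 85 were bound (24.6%; interval 20.1 to 29.5%), against 5.01% of all other nuclear genes (odds ratio 6.17; Fisher's exact test, adjusted p = 2.59e-33). Peaks at snoRNA genes made up 25 of the 100 strongest. Others were weak: the lower quartile of signal was 125 at the 82 snoRNA peaks, against 1712 at tRNA peaks. The strongest IDR peak of all, with a signal of 24700, had its summit at V 12303635, in the snoRNA gene C51F7.4, which overlaps a coding exon of frm-7, beside the intronic snoRNA gene C51F7.3. It ranked 1 in both replicates. C27H6.5, in an intron of unc-41 (V, 9970204 to 9970271), had a signal of 13741, and C27H5.9, in an intron of pdl-1 on the opposite strand (II, 7184010 to 7184078), had 9654. F30H5.4 (III, 502804 to 502889), downstream of unc-45, had 9058. With peaks near RNA polymerase III genes left out, a choice made after seeing the data, 80 snoRNA genes stayed bound.

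Spliced leader RNA genes, which supply the leader for trans-splicing, were bound in 8 of 30 cases (26.7%; Fisher's exact test, adjusted p = 0.000167), with signals of 158 at sls-2.1 and 147 at sls-2.4. The peak of sls-2.9, at 3512, had its summit in the tRNA gene M01E5.t1 (I, 13297673 to 13297745). Without peaks near RNA polymerase III genes, chosen after seeing the data, 7 of the 30 were bound (Fisher's exact test, adjusted p = 1.22e-05). In the upper 930 peaks their difference from other genes turned to -0.0768 points. Pseudogenes of tRNAs were bound in 27 of 209 cases (12.9%; Fisher's exact test, adjusted p = 2.03e-05), led by D1046.t1 at 6162 and T08B2.t1 at 4312, whose peaks also lay within 250 bp of the snoRNA genes D1046.6 and T08B2.13. Other ncRNA genes were bound in 7.29% of 8050 cases (Fisher's exact test, adjusted p = 3.92e-19). Without peaks near RNA polymerase III genes the call was lost, at 2.63% against 2.39% (Fisher's exact test, adjusted p = 0.269), and in merged loci the difference turned to -2.78 points and passed (Fisher's exact test, adjusted p = 5.34e-08). The class is led by C14F11.14 at 12277 and by R01H5.2 and F15G9.8, which overlap tRNA genes. miRNA genes (14 of 260, led by mir-2214 at 4970) and other snRNA genes (3 of 67, led by M163.13 at 7950) did not pass the threshold (Fisher's exact test, adjusted p = 0.959 and 1). In merged loci miRNA genes passed as bound less often (-5.24 points, Fisher's exact test, adjusted p = 0.0175). Merging joined genes of a class within 1000 bp and counted a locus as bound if any of its genes was. It also raised the share of the loci compared with. For the 18S, 5.8S and 26S rRNA genes, none bound, the difference went from -5.16 to -10.6 points. The turns of miRNA and other ncRNA genes in merged loci thus do not show that single genes were bound less often. Genes of piRNAs were bound in 0.228% of 15363 cases and other pseudogenes in 1.35% of 1922, both less often than other genes (Fisher's exact test, log10 of the raw p = -362 and -18.6). The test was not matched for gene length, and short genes such as those of piRNAs offer less sequence for a summit. Neighbouring piRNA genes are not independent either: in merged loci, another unit, adjusted p was 3.18e-56 by Fisher's exact test. None of 10 SmY RNA genes and none of 4 genes of 18S, 5.8S and 26S rRNA was bound; the intervals reached 30.8% and 60.2%. IDR summits lay within 250 bp of 12 of 22 mitochondrial tRNA genes. That genome carried 1 peak per 690 bp, so the planned test of the class against nuclear genes (Fisher's exact test, adjusted p = 3.32e-10) does not set these genes apart from the sequence around them.

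The replicates were compared to see how far the peaks repeat. Of the top 1860 peaks of replicate 1, 1200 (64.5%) had a summit of the top 1860 of replicate 3 within 250 bp, against 1.61% by permutation of peak positions (p = 0.001, the smallest that 1000 placements can give). The share was 92.3% in the top 930 and 43.3% in the top 3720. RNA polymerase III genes held 553 of the top 1860 peaks of replicate 1 and 562 of those of replicate 3. Across the 612 nuclear tRNA genes, the highest signals in the replicates had a Spearman's rho of 0.957 (permutation test, p = 1e-05, the smallest that 100000 permutations can give), a relation across genes, which are not independent replicates. A peak was present in both replicates at 569 tRNA genes, in replicate 1 alone at 10, in replicate 3 alone at 7 and in neither at 26.

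**Figure D3:**
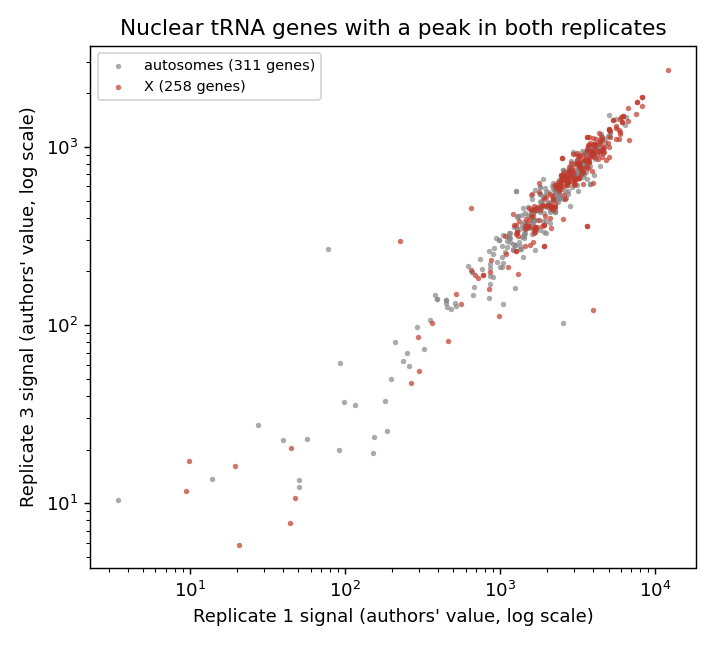
Signal at each of the 569 nuclear tRNA genes with a peak in both replicates, in replicate 1 (horizontal) and replicate 3 (vertical), the authors' values on log axes. Points for X are red and for autosomes grey; across these genes Spearman's rho was 0.950.

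Away from RNA polymerase III genes, ribosomal protein and heat shock protein genes were bound at their promoters more often than other protein-coding genes. Of 64 ribosomal protein genes 18 were bound (28.1% against 2.57%; Fisher's exact test, adjusted p = 3.61e-13), led by rpl-35 at 547 and rps-28 at 372. Of 24 heat shock protein genes 7 were bound (29.2% against 2.62%; Fisher's exact test, adjusted p = 1.03e-05), led by hsp-110 at 988 and the constitutive chaperone hsp-1 at 768. These signals were below the tRNA median of 2789. Among aminoacyl-tRNA synthetase genes 3 of 33 were bound, ears-2, iars-2 and tars-1 (9.09%; Fisher's exact test, adjusted p = 0.187). The count was 1 without replicate 1 and 2 without replicate 3, and tars-1 had no promoter peak in the list of replicate 3. Among RNA polymerase III subunit and factor genes, rpac-19 alone of 24 was bound (Fisher's exact test, adjusted p = 0.792). Single members were bound of 72 histone genes (his-37), 15 neuronal genes (snb-1) and 156 collagen genes (col-42). The snb-1 signal, 54.31, was close to the lowest of the IDR list, 54.30. Its peak ranked 2967 in replicate 1 and 11009 in replicate 3, and that of his-37 ranked 3119 in replicate 3, all outside the top 1860. None of 22 germline, 20 intestinal and 15 muscle genes was bound; by Fisher's exact test, adjusted p was 1 for these 3 lists and for histones, 0.663 for neurons and 0.337 for collagens. With promoters of 250 bp on both sides, 4 ribosomal protein genes were bound and the call was lost (Fisher's exact test, adjusted p = 0.103); in the upper 930 peaks 4 of them and 4 heat shock protein genes were bound and both lists still passed (Fisher's exact test, adjusted p = 0.00215 and 8.5e-05). In the top peaks of replicate 3 alone, 10 ribosomal protein genes were bound (15.6%; Fisher's exact test, adjusted p = 1.68e-06), and 3 RNA polymerase III subunit and factor genes were bound and the list passed (Fisher's exact test, adjusted p = 0.0343).

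In all, 1248 nuclear IDR peaks lay at least 500 bp from RNA polymerase III genes and tRNA pseudogenes. Promoters held 422 of them (33.8%), against 13.8% by random placement (2.46-fold, one-sided permutation of peak positions, p = 0.001, the smallest that 1000 placements can give). Draws from the relaxed pooled list were not made for promoters. At RNA polymerase III genes such draws lowered the fold from 72.9 to 14.1, so the promoter fold holds only against uniform placement. The 422 promoter peaks marked 529 of 19971 protein-coding genes (2.65%), with a median signal of 85.5 per peak. The number of genes was 326 with 250 bp on both sides and 110 in the upper 930 peaks. The strongest lay upstream of T13C5.6 (X, signal 12277, at the ncRNA gene C14F11.14). Of the 10 genes with the highest signals, W01D2.3 (6316) and ZK816.3 (4628) likewise had no snoRNA gene within 250 bp of the summit. Neither peak was among the 52 of at least 1712 without an annotated RNA gene within 250 bp, so each lay near an RNA gene of another class. The other genes of the 10 shared their peaks with snoRNA genes: chst-1 and C41C4.9 with C41C4.11 (II, 7952), Y75B12B.11 with Y75B12B.12 (V, 7647), K02C4.2 with K02C4.8 (7016), wrt-3 with F38E11.14 (6603), F55A11.11 with F55A11.10 (6569) and gst-27 with Y53F4B.48 (4788).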

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

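No test in this part was chosen after the result was seen. A signal lay outside nuclear chromatin: the mitochondrial genome, whose tRNA genes entered the class comparison, carried 20 IDR peaks over 13.8 kb, or 1 peak per 690 bp. Their median signal was 1356, and the lists of replicates 1 and 3 held 21 and 19 peaks there. No explanation for these peaks was tested.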

How the results depend on the processing

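The tests chosen after the data were seen were those of gene classes with peaks away from RNA polymerase III genes, of promoters also away from small RNA genes, of isotypes outside repeated sequence, and of the replicates' rho at other distances or over shared genes. Of the alternatives for the main comparisons, 51 kept the direction and the side of the threshold or stayed within 1.5 times the count, among them the bound tRNA genes (532 to 570) and the signal, B-box and replicate comparisons. The top 1860 pooled peaks are the IDR peaks themselves, so that alternative, counted among the 51, tests nothing. Promoter-bound genes numbered 326 with 250 bp on both sides and 110 in the upper 930 peaks, which follows from the shorter window and list; without a replicate they numbered 380 to 515. The isotype shares did not differ past the threshold at 500 bp or in merged loci (permutation test, p = 0.12 and 0.29). The isotype permutation test passed at 100 bp (permutation test, p = 0.0062) and without a replicate (permutation test, p = 0.008 to 0.042). The X comparison passed in merged loci (4.79 points), where a locus with any bound gene counted as bound, so the unit differs from single genes. The cause of these changes was not tested. The difference for X turned to -0.608 points at 100 bp, and that for tRNA genes inside protein-coding genes to -0.0193 points at 500 bp. Among single classes, the difference in points from other genes turned for miRNA genes at 100 bp (-1.79), in the upper 930 peaks (-1.50) and in merged loci (-5.24, which passed), for other ncRNA genes in merged loci (-2.78, which passed) and for spliced leader RNA genes in the upper 930 peaks (-0.0768). Merging raised the share bound among the loci compared with, so turns in merged loci do not compare like units. The difference also turned for other snRNA genes without replicate 3 (2.28, against -3.68 without replicate 1) and away from RNA polymerase III genes (2.05). Protein-coding genes (0.172 points, not past the threshold) turned and passed at 100 bp (-0.885) and in the upper 930 peaks (-1.77), turned without passing in merged loci (-0.890), and passed in the other direction at 500 bp (1.23), without replicate 1 (0.484) and away from RNA polymerase III genes (2.56). Among promoter lists it turned for neurons with 250 bp on both sides (-1.63), in the upper 930 peaks (-0.551) and without a replicate (-2.58 to -1.90), for muscle without a replicate (4.09 to 4.77), for intestine with 1000 bp upstream (1.61) and without replicate 3 (2.42, against -1.90 without replicate 1), and for histones in the upper 930 peaks (0.841); the cause was not tested. No paired analysis was possible because there is a single group. Depth is unknown and limits which weak peaks could be called.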

Other observations

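Tests chosen only after results were seen were those of signal on X, of snoRNA strand, of repeated sequence at part of the genes or peaks, of protein-coding promoters, of neighbouring genes and of peaks in any relaxed list; the bootstrap intervals and the 70% limit for repeated sequence were also set then. Bound tRNA genes had higher signals on X than on autosomes. The median IDR signal was 3453 on X and 2515 on autosomes, a ratio of 1.37 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). Neighbouring genes sharing a peak, such as F15G9.t1 and F15G9.t2, each entered with its signal. The test was not repeated by peak or merged locus. Over all tRNA genes with a peak in a replicate's own list, which is another set, the ratio was 1.34 in replicate 1 (265 genes on X, 314 on autosomes) and 1.34 in replicate 3 (262 and 314; permutation test, p = 1e-05 and 6e-05). Bound snoRNA genes were found in introns on either strand of the host: 29 of 141 on the same strand were bound (20.6%) and 13 of 27 on the opposite strand (48.1%; Fisher's exact test, two-sided, p = 0.00616). The strongest peak without an annotated RNA gene, picked after its value was seen, had its summit at II 8441698 in an intron of lips-10, with a signal of 8841.

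Some snoRNA genes carried peaks as strong as those of tRNA genes. Neighbouring RNA polymerase III genes do not account for this, since 94.1% of the bound snoRNA genes (interval 86.8 to 98.1%) stayed bound without peaks near such genes. Nor do protein-coding promoters, where 14.1% of their summits lay (interval 7.51 to 23.4%). A B-box in the gene or 150 bp upstream was 34.6 percentage points more frequent in bound snoRNA genes (40% of 85) than in unbound ones (5.36% of 261; Fisher's exact test, p = 1.85e-13). As a hypothesis, part of these genes may have RNA polymerase III promoters of their own; bound genes without a match stay unexplained, and repeated sequence was not tested here.

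Of 536 IDR peaks with a signal of at least 1712, the lower quartile at tRNA genes, 52 had no annotated RNA gene within 250 bp, and these were all among the top 1860 peaks of both replicates. A B-box lay within 100 bp of 40.4% of these summits, 35.6 percentage points more than in the windows to either side (McNemar's exact test, p = 6.6e-05), and 9.62% lay in protein-coding promoters (interval 3.2 to 21.03%). The median percent of unique 36-base words was 1.93 points above that at tRNA gene summits (permutation test, p = 2e-05, bootstrap interval -21.2 to 10.7). Since that interval is wide, the median leaves repetition open. The permutation p-value also responds to a difference in spread between the groups, so it does not show that the medians differ. Fewer than 70% unique words surrounded 21 of the 52, 37.01 points more than at tRNA gene summits (Fisher's exact test, p = 2.46e-14). Of the 31 peaks in less repeated sequence 17 had a B-box, so as a hypothesis unannotated RNA polymerase III genes may lie at part of these peaks. Some of the 17 lay in the same gene, as in gfrl-1 and in sms-3, and are not separate loci. Reads from copies elsewhere could have raised peaks in repeated sequence. That is opposite to the loss of shared reads considered below. The handling of such reads is not given, and neither gain nor loss was measured. The rest of the 31 are explained by neither account, among them the strongest peaks, in introns of lips-10 (8841) and srt-52 (8039).

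The 47 unbound tRNA genes did not lack a B-box: 91.5% had one, 4.23 points more than bound genes (Fisher's exact test, p = 0.496; bootstrap interval -4.99 to 12.03). A summit of the relaxed pooled list lay at 23.4% of them (interval 12.3 to 38.0%). One of the pooled or a replicate's list lay at 46.8% (22 of 47, interval 32.1 to 61.9%). Random placement gave 31.8% (one-sided permutation of positions, p = 0.027), so peaks under the threshold stay open for part of them. Not all of the 22 had weak peaks: ZK678.t5 and Y7A5A.t3 had replicate 3 signals of 543 and 159. Neither had a summit within 250 bp in the replicate 1 or pooled list. In replicate 3 the median over tRNA genes was 534. The median percent of unique 36-base words at the 47 unbound genes differed by -4.86 points from that of bound genes (permutation test, p = 4e-05, bootstrap interval -11.7 to 3.91). That interval is too wide to exclude shared reads for the set as a whole. Here too the p-value responds to spread and does not show that the medians differ. Repeated sequence surrounded 16 of the 47, 29.97 points more often than bound genes (Fisher's exact test, p = 1.15e-09), among them 4 His genes on X, so as a hypothesis loss of reads shared between copies may account for part of the unbound genes; the rest stay unexplained, and no biological explanation was tested.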
